A study of Gallus gallus with 6 samples.

How the data were processed

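RNA was taken from chicken lens explants that had been cultured after a cataract-type operation and treated with DMSO or GSK-J4 from day 1 to day 3, and 150 bp paired-end reads were sequenced, per the labels' protocols. Cultures were held at 37 degrees Celsius and 5% CO2 in medium with 10% fetal bovine serum. The labels speak both of total RNA as the input and of mRNA sequencing, and the selection step of the library kit is not given in the sources used here. Groups and replicate numbers came from the sample titles, 3 libraries per group. Nothing in the labels says whether the libraries of a group came from separate animals or separate cultures, so p-values measure only the spread between these samples, part of which may be technical. W-linked counts differed between libraries of a group, which therefore did not hold the same mix of sexes, and the number of animals behind each library is not given in the sources used here.

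The deposited count table holds whole-number counts per gene, not normalised, for 24356 genes in the 6 libraries. The deposited FPKM table holds values that the authors made from those counts, as checked on the values themselves: each equals the count divided by gene length and by 1 factor per library, which corresponds to a library total of 0.874 to 0.979 of the summed counts. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3, StringTie 1.3.3b and DESeq2 1.20.0 without saying what each was used for. The genome build, the annotation release and whether counting used the strand are not given in the sources used here, so reads of overlapping and antisense genes, and of near-identical copies such as the actin genes, may be split between genes in a way that cannot be checked. Coordinates are those of the deposited tables. Gene symbols were those of the tables for 13688 genes, and another 725 were added by matching NCBI or RefSeq identifiers in the tables' descriptions to a RefSeq gene table of assembly GRCg7b, which was used for names only. The other 9943 genes kept their Ensembl identifiers.

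Library totals were 16950835, 17308741 and 15456888 for DMSO replicates 1, 2 and 3, and 15771410, 22541756 and 14862268 for GSK-J4 replicates 1, 2 and 3. A chi-square comparison of counts within each group gave 10.9 to 35.5 per degree of freedom for the 6 pairs, so each pair differed by more than sampling noise and all libraries were counted separately. In the edgeR fit, the biological coefficient of variation was 16.9%, which was the limit on precision for all but the lowest genes.

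Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filterByExpr (12583 of 17951 with any count), libraries were scaled by TMM factors, and GSK-J4 was compared with DMSO by the robust quasi-likelihood F test with treatment as the only factor. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called, with no minimum fold, and those with a log2 fold change of at least 1 in size were counted separately. Log2 fold changes are GSK-J4 minus DMSO. Their standard error is the size of the log2 fold change divided by the square root of F, and 95% intervals follow from it. CPM are TMM-normalised, with the mean and SD over 3 libraries. A prior count of 2 was used for log2 CPM in correlations and principal components.

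The 36 gene lists were written from textbook knowledge before the data were examined, as were the tests, the alternatives and the rule for named genes. They cover the histone demethylases targeted, Polycomb, HOX and developmental regulators, contractile, matrix and mesenchymal genes, TGF-beta and other signalling, lens fibre and epithelial cells, other cell types of the eye and blood, the cell cycle, p53, stress pathways, hypoxia, cholesterol, inflammation, interferon, mitochondria and ribosomes. The 34 lists with at least 3 tested members were tested in limma 3.58.1 with camera at a preset correlation of 0.01 between genes, which compares a list with all other genes, and again with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the lists. Some genes stand in more than 1 list. Named genes were the 12 with the largest rise and the 12 with the largest fall among called genes with a symbol, a mean of at least 5 CPM and no overlap between groups, then up to 4 members of each list with the smallest p, and then KDM6A, KDM6B, EZH2, ACTA2, TAGLN, COL1A1, COL1A2, FN1, TGFB1, TGFB2, PAX6, CRYAA and MIP where measured. Other genes are marked where they appear as named after their values were seen. Some genes that the rule takes are not reported here by name, though they stay in the counts.

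The alternatives were DESeq2 size factors, upper-quartile factors and library totals in place of TMM, no filter and a filter of more than 1 CPM in 3 libraries, DESeq2 1.42.0 and limma-voom as the test, limma-trend on log2(FPKM + 0.1) and log2(FPKM + 1) for genes with a mean FPKM of at least 0.5, the replicate number as a block, robust estimation turned off, and leaving out each library in turn. A fit without the genes of chromosomes Z, W and MT was added after the data were seen. Fold changes on the log2(FPKM + pseudocount) scale understate the change of low genes. The scripts were tested on simulated counts for the comparison of GSK-J4 with DMSO. These used the means and depths of these libraries, with the dispersion typical of each gene's level. Single genes did not depart from that dispersion, and no difference between replicates or in the mix of sexes was simulated. The rates found there may therefore not hold for these data. Of the genes tested there (12437), the fit recovered 76 of 98 (77.6%) changed 2-fold and 91 of 95 (95.8%) changed 4-fold, 6 of 173 calls (3.47%) were false, and a simulation with no changed gene gave 0 calls at 12434 genes. Camera found the 1 list that was shifted and called 0 of 30 lists that were not. Genes were drawn there independently of each other, so camera's result holds only where members of a list do not vary together. In the data, the estimated correlation was 0.58 in the mitosis list and 0.38 in the contractile list. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.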

Results

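Gene expression was measured by RNA sequencing in chicken lens explants, which were kept in culture after an operation that mimics cataract surgery, an injury after which lens cells left on the capsule can multiply and turn into contractile, matrix-producing cells. The explants received either the vehicle DMSO or GSK-J4, a cell-permeable inhibitor of the histone demethylases KDM6A and KDM6B, on each day from day 1 to day 3 after injury. There were 3 libraries per group, with between 14862268 (GSK-J4 replicate 3) and 22541756 (GSK-J4 replicate 2) counts assigned to genes. Crystallins, the main proteins of the lens, took 21.6% ± 1.39 (SD, n = 3) of the counts with DMSO and 24.4% ± 1.67 (SD, n = 3) with GSK-J4. In a principal component analysis of the 12583 tested genes, the first component held 47.3% of the variance, with DMSO libraries between -41.2 and -17.7 and GSK-J4 libraries between 17.5 and 39.9. Correlations of log2 CPM across genes were 0.973 to 0.977 within DMSO, 0.976 to 0.983 within GSK-J4 and 0.948 to 0.975 between the groups. The libraries also differed in a way that the groups did not explain. The summed CPM of 34 genes of the female-specific chromosome W was 389, 935 and 906 in DMSO replicates 1, 2 and 3, 348 and 760.0 in GSK-J4 replicates 1 and 2, and 15.1 in GSK-J4 replicate 3.

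The question was which genes of the injured lens respond to GSK-J4. The metallothionein gene MT4L, whose protein binds zinc and copper, rose 12.7-fold with GSK-J4, from 14.9 ± 1.35 to 189.5 ± 30.2 CPM (SD, n = 3 each). CHAC1, a glutathione-degrading enzyme of the stress response, rose 5.98-fold, from 13.8 ± 2.25 to 82.5 ± 5.90 CPM (SD, n = 3 each). In the other direction, the smooth muscle actin gene ACTG2 was 20.7-fold lower, at 268 ± 65.0 CPM with DMSO and 13.1 ± 3.28 CPM with GSK-J4 (SD, n = 3 each), and the collagen VI gene COL6A2 was 13.3-fold lower. Fewer genes rose than fell. Of 12583 genes tested with edgeR's quasi-likelihood test, 132 were higher and 502 were lower at an adjusted p below 0.05, and 44 and 360 of these changed at least 2-fold. All 634 had CPM ranges that did not overlap between the groups, as did 3055 (24.3%) of all tested genes, against 10% by chance. The count fell to 366 without DMSO replicate 3, to 249 without GSK-J4 replicate 2 and to 278 without GSK-J4 replicate 3, and 346, 245 and 274 of these were among the 634. The number of higher genes was 271 without DMSO replicate 2, and 68, 46 and 42 without DMSO replicate 3, GSK-J4 replicate 2 and GSK-J4 replicate 3.

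**Figure D1:**
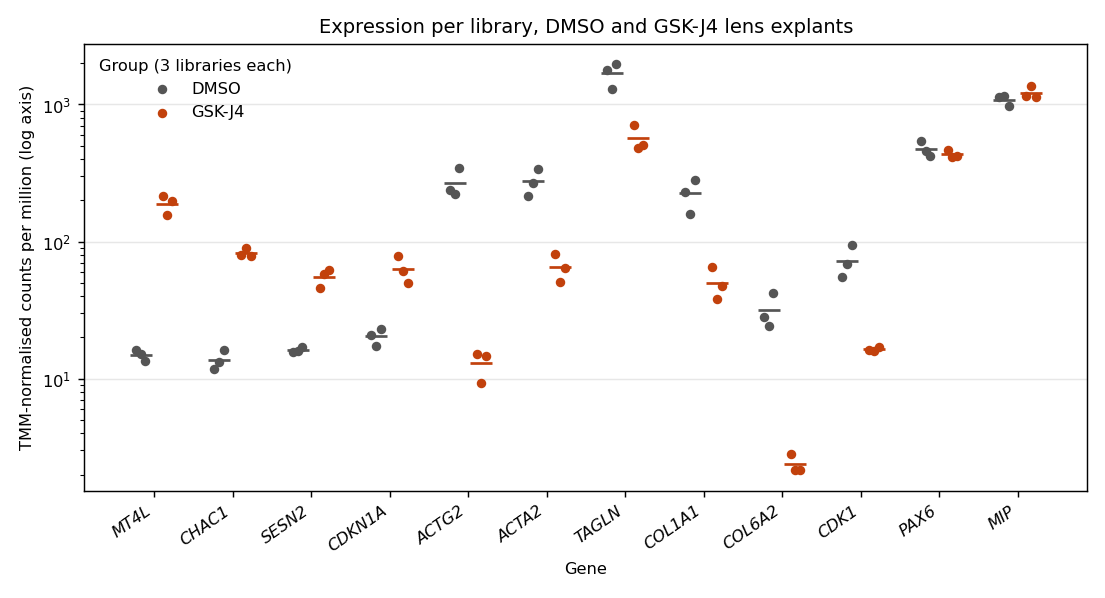
TMM-normalised CPM on a log axis for 12 genes, with 1 point for each of the 3 DMSO (grey) and 3 GSK-J4 (orange) libraries and a bar at each group mean. MT4L, CHAC1, SESN2 and CDKN1A were higher and ACTG2, ACTA2, TAGLN, COL1A1, COL6A2 and CDK1 lower in all 3 GSK-J4 libraries than in any DMSO library, while PAX6 and MIP overlapped between the groups.

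By the rule for the largest changes, the genes that rose most after MT4L (log2 fold change 3.67, SE 0.15) and CHAC1 (2.58, SE 0.15) were MAT1A (2.35), PSPH (2.03), PSAT1 (1.89), PCSK6 (1.84), SESN2 (1.77), GPT2 (1.75), CDKN1A (1.63), TSC22D3 (1.58), IL-18 (1.54) and ASNS (1.48). PSPH and PSAT1 encode enzymes of serine synthesis, ASNS one of asparagine synthesis and MAT1A one that forms S-adenosylmethionine. The genes that fell most were ACTG2 (-4.37, SE 0.23), ACTC1 (-3.88), FBN3 (-3.82), ITGA8 (-3.74), COL6A2 (-3.73, SE 0.25), CRIP1 (-3.07), NRP1 (-3.05), ALDH1A3 (-2.98), KLF9 (-2.98), FST (-2.77), COL6A1 (-2.76) and NEFL (-2.69). They include actins of muscle, a fibrillin, an integrin subunit of contractile cells, the retinoic acid-forming enzyme ALDH1A3 and the activin antagonist FST. In edgeR, adjusted p was 1.2e-06 for MT4L, 8.2e-06 for CHAC1, 6.5e-06 for ACTG2 and 2.7e-05 for COL6A2. The file places MT4L (ENSGALG00000028451) on chromosome 11 at 2118766 to 2120425, ACTG2 (ENSGALG00000041634) on chromosome 22 at 3827641 to 3830849, and the collagen VI genes COL6A1 (ENSGALG00000005974) and COL6A2 (ENSGALG00000039216) on chromosome 7 at 6741231 to 6760769 and 6782467 to 6808501, with a genome build not given in the sources used here. The weakest calls were those of ASNS (adjusted p = 0.0488), which reached 0.23 without DMSO replicate 3 and was above 0.05 in 5 of 6 fits that left out a library, and of PSAT1 (adjusted p = 0.0492), which reached 0.16 without DMSO replicate 3 and was above 0.05 in 4 of them. Both calls were also lost under each of 3 other scalings, with adjusted p of 0.056 to 0.072 for ASNS and 0.054 to 0.079 for PSAT1. GPT2 was not called without GSK-J4 replicate 2 (adjusted p = 0.058) or 3 (0.056), nor CRIP1 without DMSO replicate 1 (0.065).

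Genes of the contractile apparatus of myofibroblasts were lower for 14 of 24 tested members, with 0 higher and 10 not called, or 17 lower adjusted over the list alone. The count was 8 without GSK-J4 replicate 2 and 8 without GSK-J4 replicate 3. The median log2 fold change was -0.83, with 3 members above 0. ACTA2, the alpha-smooth muscle actin that marks myofibroblasts, fell from 275 ± 62.9 to 65.2 ± 14.8 CPM (SD, n = 3 each), and the actin-binding gene TAGLN from 1683 ± 350.2 to 567 ± 125 CPM (SD, n = 3 each). Their log2 fold changes were -2.08 and -1.57, and edgeR's adjusted p was 0.00025 and 0.00072. CNN2 (-1.65) and LMOD1 (-2.06), which bind actin or tropomyosin, fell as well. MYH11 (0.00), MYLK (-0.09) and CNN1 (-0.28), named after their values were seen, were not called. The shift of the list had an adjusted p of 1.6e-29 in camera, and adjusted p = 0.0849 with an estimated correlation. Actin genes are near-identical in sequence, so the split of reads between ACTG2, ACTA2, ACTC1 and ACTA1 is uncertain. In the list of striated muscle cell markers, 3 of 7 tested genes were lower, also adjusted over the list alone, namely the actins ACTC1 and ACTA1 (-1.96) and the troponin gene TNNI2 (-2.62), while TNNT2 (0.00) and TNNC1 (-0.07), named after their values were seen, were not called. That list had a median of -0.66 (-1.03 without GSK-J4 replicate 2), a camera adjusted p of 1.2e-09 and adjusted p = 0.0849 with an estimated correlation. Only 7 of its 23 deposited genes passed the filter on low counts.

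Genes of the fibrous extracellular matrix were lower for 16 of 38 tested members, with 0 higher and 22 not called. Adjusted over the list alone, 24 were lower and 1 was higher. The fibrillar collagen genes COL1A1 (-2.16, SE 0.23) and COL1A2 (-2.49, SE 0.27) fell, COL1A1 from 225 ± 61.7 to 50.3 ± 13.9 CPM (SD, n = 3 each), and so did COL6A1 and COL6A2. FN1, which encodes fibronectin, fell by 1.96 on the log2 scale (edgeR adjusted p = 0.0036), but was not called without DMSO replicate 1 (adjusted p = 0.057). Not every matrix gene was lower. DCN (0.03), TNC (-0.07), FBN1 (0.27) and SPARC (0.38), named after their values were seen, were not called. The median of the list was -0.79, with a camera adjusted p of 7.8e-17 and adjusted p = 0.0849 with an estimated correlation. Regulators and markers of the mesenchymal transition were lower for 8 of 21 members, with 0 higher and 13 not called. Adjusted over the list alone, 12 were lower and 1 was higher. The transcription factor gene TWIST1 (-3.91, SE 0.45), the collagen-binding integrin gene ITGA11 (-1.98) and the calcium-binding protein gene S100A6 (-0.97) fell, whereas VIM (0.08), CDH2 (0.01), ZEB1 (0.25) and PDGFRA (0.20), named after their values were seen, were not called. The count of lower genes was 4 without GSK-J4 replicate 2. Camera gave an adjusted p of 9.7e-09 for a list median of -0.64 (-0.99 without GSK-J4 replicate 1), and adjusted p = 0.188 with an estimated correlation.

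Components and targets of TGF-beta signalling, a driver of the contractile change in lens cells, were lower for 8 of 26 members, 0 were higher and 18 were not called, or 10 lower adjusted over the list alone. The count was 5 without DMSO replicate 3, 2 without GSK-J4 replicate 2 and 3 without GSK-J4 replicate 3. TGFB3 fell from 195 ± 2.66 to 97.1 ± 9.83 CPM (SD, n = 3 each) and the target gene CTGF from 563 ± 133 to 271 ± 30.8 CPM (SD, n = 3 each). Their log2 fold changes were -1.01 and -1.05, with edgeR adjusted p of 0.00045 and 0.0036. TGFB2 did not pass the test (0.02, adjusted p = 0.958). TGFB1 was called at -0.90 (adjusted p = 0.020) with all libraries but not without DMSO replicate 1 (0.052), DMSO replicate 3 (0.054), GSK-J4 replicate 2 (0.13) or GSK-J4 replicate 3 (0.11). The list median was -0.26, against -0.15 without DMSO replicate 3 and -0.13 without GSK-J4 replicate 2, with a camera adjusted p of 6.2e-05 and adjusted p = 0.276 with an estimated correlation. Among matrix proteases and their inhibitors, 3 of 20 were lower, 0 were higher and 17 were not called, or 8 lower and 1 higher adjusted over the list alone, and 5 were lower without DMSO replicate 1 or 2. With all libraries, these were TIMP3 (-1.45), the gelatinase gene MMP2 (-2.02) and ADAMTS9 (-1.89), the last of which was lost without DMSO replicate 3 (0.11), GSK-J4 replicate 2 (0.13) or GSK-J4 replicate 3 (0.10). That list had a median of -0.43, a camera adjusted p of 0.0073 and adjusted p = 0.215 with an estimated correlation. Of 12 basement membrane genes of the lens capsule, 1 was higher and 3 were lower, or 1 and 4 adjusted over the list alone. They were the laminin gene LAMA3 (0.63) on the one side and COL4A1 (-0.77), COL4A2 (-0.74) and AGRN (-1.24) on the other, each lost without DMSO replicate 3, GSK-J4 replicate 2 or GSK-J4 replicate 3, where adjusted p reached 0.10, 0.22, 0.14 and 0.093, and COL4A1 and AGRN also without DMSO replicate 1 (0.12 and 0.053). The median of this list was 0.00 and its mean -0.14, and camera gave an adjusted p of 0.632.

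**Figure D2:**
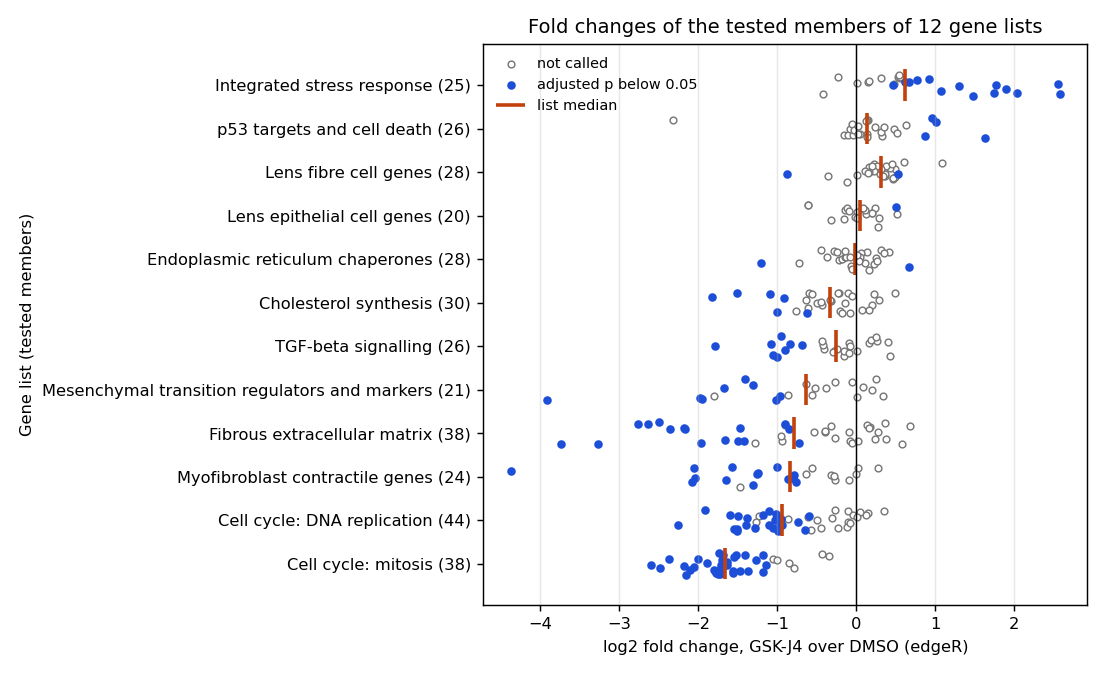
Log2 fold change of GSK-J4 over DMSO in edgeR for each tested member of 12 gene lists, with the number of members in brackets, filled points for an adjusted p below 0.05, open points for genes not called and an orange bar at the list median. The stress response median lies at 0.62, the mitosis and DNA replication medians at -1.66 and -0.94, and the contractile, matrix and mesenchymal medians at -0.83, -0.79 and -0.64.

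Of 38 tested cell cycle genes that act in mitosis, 32 were lower, 0 were higher and 6 were not called, or 37 lower adjusted over the list alone, with a median log2 fold change of -1.66. The mitotic kinase genes PLK1 (-2.60, SE 0.17) and CDK1 (-2.15, SE 0.19) fell, CDK1 from 72.8 ± 20.3 to 16.4 ± 0.526 CPM (SD, n = 3 each), as did BUB1B (-2.37) and ANLN (-2.48), which act in the spindle checkpoint and in cytokinesis. Of 44 DNA replication genes, 24 were lower, 0 were higher and 20 were not called, or 29 lower adjusted over the list alone, with a median of -0.94. The count was 13 without DMSO replicate 3, 12 without GSK-J4 replicate 2 and 12 without GSK-J4 replicate 3. Examples were the replicative helicase genes MCM5 (-1.51) and MCM2 (-1.18), RRM2 (-1.59), which supplies deoxynucleotides, and UHRF1 (-1.92), which maintains DNA methylation. Camera gave adjusted p of 1.1e-79 for mitosis and 4.8e-23 for replication, against adjusted p = 0.0849 with an estimated correlation for mitosis and adjusted p = 0.150 with an estimated correlation for replication. Among p53 targets and cell death genes, 4 of 26 were higher, 0 were lower and 22 were not called. Adjusted over the list alone, 4 were higher and 1 was lower. CDKN1A, the inhibitor of cyclin-dependent kinases, rose from 20.4 ± 2.87 to 63.2 ± 14.4 CPM (SD, n = 3 each), with an edgeR adjusted p of 0.00051. MDM2 (0.96) and CCNG1 (0.87) also rose. The list median was 0.14, with a camera adjusted p of 0.00059 and adjusted p = 0.0849 with an estimated correlation.

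Genes of the integrated stress response, which ATF4 drives when translation initiation is slowed, rose for 14 of 25 tested members, with 0 lower and 11 not called, or 19 higher adjusted over the list alone. The count was 6 without GSK-J4 replicate 2 and 7 without GSK-J4 replicate 3. The median log2 fold change was 0.62. Besides CHAC1, PSPH and the ATF4 gene (0.62), SESN2 rose from 16.2 ± 0.714 to 55.3 ± 8.29 CPM (SD, n = 3 each) and CTH, which makes cysteine, from 35.2 ± 2.13 to 86.7 ± 21.4 CPM (SD, n = 3 each). In edgeR, adjusted p was 0.00011 for SESN2 and 0.0016 for CTH. ATF4 was named after its value was seen. Camera gave an adjusted p of 4.8e-23, and adjusted p = 0.0849 with an estimated correlation. The endoplasmic reticulum chaperone list did not shift (median -0.02, camera adjusted p = 0.714). In it, 1 of 28 genes was higher and 1 lower, or 2 and 4 adjusted over the list alone. These were XBP1 (0.67), lost without GSK-J4 replicate 2 (0.10) or 3 (0.084), and CREB3L1 (-1.21), lost without GSK-J4 replicate 2 (0.056). Without DMSO replicate 1, 3 genes of the list were lower. In the list of heat shock and proteostasis genes, HSP90AB1 (-0.50) was the 1 lower gene of 22, also adjusted over the list alone, with 0 higher and a camera adjusted p of 0.445. Its call was lost in 5 of 6 fits that left out a library, with adjusted p up to 0.17 without GSK-J4 replicate 2, and kept only without DMSO replicate 3.

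Of 26 genes of the oxidative stress and metal response, 3 were higher, 1 was lower and 22 were not called, or 7 and 2 adjusted over the list alone. The metallothionein gene MT3 rose from 21.8 ± 2.94 to 55.7 ± 3.61 CPM (SD, n = 3 each), with an edgeR adjusted p of 0.00031. The cystine transporter gene SLC7A11 (2.55) and the transferrin receptor gene TFRC (0.98) rose, and ME1 (-0.92), an NADPH-forming enzyme, fell with all libraries but was lost without GSK-J4 replicate 3 (adjusted p = 0.068). The list median was 0.13, with a camera adjusted p of 0.0034 and adjusted p = 0.215 with an estimated correlation. Cholesterol synthesis genes were lower for 6 of 30 members, with 0 higher and 24 not called. Adjusted over the list alone, 12 were lower and 2 were higher. The count of lower genes was 3 without DMSO replicate 3, 1 without GSK-J4 replicate 2 and 3 without GSK-J4 replicate 3. FDPS, which makes farnesyl pyrophosphate, fell from 86.5 ± 22.2 to 43.3 ± 1.06 CPM (SD, n = 3 each), with an edgeR adjusted p of 0.0060. NSDHL (-1.82) fell too, but was lost without DMSO replicate 3 (0.055) or GSK-J4 replicate 2 (0.080). The list median was -0.33, with a camera adjusted p of 0.00010 and adjusted p = 0.336 with an estimated correlation. In the hypoxia and glycolysis list, 1 of 41 genes was higher (BNIP3, 0.48) and 1 lower (EPAS1, -1.05), or 1 and 4 adjusted over the list alone. Both calls were lost without DMSO replicate 1, DMSO replicate 3, GSK-J4 replicate 2 or GSK-J4 replicate 3, and that of BNIP3 also without GSK-J4 replicate 1, with adjusted p up to 0.18 and 0.20. The list had 2 lower genes without DMSO replicate 1, and 2 higher and 4 lower without DMSO replicate 2. The median of that list was 0.14 (0.08 without GSK-J4 replicate 3) and its mean -0.01, with a camera adjusted p of 0.529.

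Lens fibre cell genes differed little for single genes, but mostly in one direction. Of 28 tested members, 25 had a positive fold change, 1 was called higher, 1 lower and 26 were not called, or 6 higher and 1 lower adjusted over the list alone. The number of higher genes was 4 without DMSO replicate 1, 2 without GSK-J4 replicate 1, and 0 without DMSO replicate 3, GSK-J4 replicate 2 or GSK-J4 replicate 3. The lower gene was FABP5, which encodes a fatty acid-binding protein, at a log2 fold change of -0.88, and its call was lost without any one of the 3 GSK-J4 libraries (adjusted p up to 0.077). MIP (0.17, adjusted p = 0.482), the fibre water channel, was not called. Camera gave an adjusted p of 0.00023 for a median of 0.31, and adjusted p = 0.215 with an estimated correlation. Of 20 lens epithelial genes, 1 was higher and 0 were lower, also adjusted over the list alone, with a median of 0.05 and a camera adjusted p of 0.445. It was the connexin gene GJA1 (0.50), lost in 5 of 6 fits that left out a library, all but that without DMSO replicate 2, with adjusted p up to 0.14 without GSK-J4 replicate 3. The eye field transcription factor gene PAX6 (-0.14, adjusted p = 0.587) and CRYAA (0.20, adjusted p = 0.456), the alpha-crystallin gene, were not called.

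Of the drug's targets, KDM6A was at 39.1 ± 2.50 CPM with DMSO and 39.8 ± 2.85 CPM with GSK-J4 (SD, n = 3 each), and KDM6B was not analysed here. The log2 fold change of KDM6A was 0.02, with a 95% interval of -0.24 to 0.29. Of 27 subunits of the Polycomb repressive complexes, which write and read the histone mark that KDM6A removes, 1 was higher and 0 were lower, also adjusted over the list alone. It was PCGF3 (0.77), lost without DMSO replicate 3 (adjusted p = 0.091), GSK-J4 replicate 2 (0.075) or GSK-J4 replicate 3 (0.14). PCGF3 lies on chromosome Z, at 12.2, 14.1 and 12.8 CPM in DMSO replicates 1, 2 and 3. In GSK-J4 replicates 1, 2 and 3 it was at 19.0, 20.2 and 27.5 CPM. Replicate 3 of GSK-J4 was the library with the lowest W-linked sum (15.1 CPM). A part of the mix of sexes in the rise of PCGF3 was not tested. EZH2, the methyltransferase gene, was not called at -0.66 by edgeR (adjusted p = 0.068) but was by DESeq2 (adjusted p = 0.017), as well as under the upper-quartile (0.040) and library total (0.025) scalings. EdgeR also called EZH2 with the replicate block (adjusted p = 0.018) and without a filter (0.021). The list had a median of 0.05 and a camera adjusted p of 0.529. Of 85 developmental regulators in the tables that often carry the mark, only 11 passed the filter on low counts, so they do not stand for the silent ones. Of these 11, 10 had a negative fold change and 1 was lower with 0 higher, or 3 lower adjusted over the list alone. It was EMX2 (-2.49), lost without DMSO replicate 3 or any one GSK-J4 library (adjusted p up to 0.10), while 2 genes were lower without DMSO replicate 2. The list median was -0.54, with a camera adjusted p of 0.013 and adjusted p = 0.336 with an estimated correlation. Of the 35 HOX genes in the tables, 0 passed the filter on low counts.

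Markers of other cell types that an explant could hold were mostly at low levels. Among the deposited genes, 16 of 33 macrophage, 8 of 26 leukocyte and 5 of 23 neural retina markers passed the filter on low counts. So did 3 of 10 myogenic mesenchymal, 7 of 15 endothelial, 11 of 19 pigmented and ciliary and 3 of 13 red blood cell markers. The tested markers do not stand for the rest. Of 16 tested macrophage markers, 8 leukocyte markers and 5 neural retina markers, edgeR and DESeq2 called 0, and 0, 1 and 0 had an unadjusted p below 0.05. Their medians were -0.30, 0.00 and -0.06, with camera adjusted p of 0.632, 0.632 and 0.716, the leukocyte mean was -0.31, and camera's direction for retina was up. The macrophage median was 0.07 without DMSO replicate 1, -0.52 without DMSO replicate 3 and -0.17 without GSK-J4 replicate 3, and the retina median 0.27 and -0.32 without DMSO replicates 1 and 3. Without DMSO replicate 3, the macrophage list was shifted down with the preset correlation (camera adjusted p = 0.0085), and with all libraries it had adjusted p = 0.810 with an estimated correlation. CSF1R, the macrophage growth factor receptor gene, was at 3.39 ± 2.15 CPM with DMSO and 1.47 ± 1.13 CPM with GSK-J4 (SD, n = 3 each). Of 3 genes of a myogenic mesenchymal cell population of the lens, 0 were called by either tool or had an unadjusted p below 0.05, with a median of -0.27 and a camera adjusted p of 0.529. That median was -0.48 without DMSO replicate 3, and -0.49, -0.78 and -0.11 without GSK-J4 replicates 1, 2 and 3. Among 7 endothelial markers, the vascular endothelial growth factor receptor genes FLT1 (-1.90) and FLT4 (-0.87) were lower and 0 were higher, also adjusted over the list alone, with a median of -0.05 (0.21 without DMSO replicate 1 and -0.35 without DMSO replicate 2) and a camera adjusted p of 0.223. Both were lost without DMSO replicate 3 or GSK-J4 replicate 2, with adjusted p up to 0.16 and 0.21, FLT1 also without GSK-J4 replicate 1 and FLT4 without DMSO replicate 1 or GSK-J4 replicate 3. Among 11 markers of pigmented and ciliary epithelium, the water channel gene AQP1 (-1.54, edgeR adjusted p = 0.0033) was lower and 0 were higher, also adjusted over the list alone, with a median of -0.07 (0.14 without DMSO replicate 1 and -0.33 without DMSO replicate 3) and a camera adjusted p of 0.632. Of 3 red blood cell markers, 1 was higher, or 2 adjusted over the list alone, and 0 were lower. It was TFRC, which other cells also express, while ALAS2 (-0.34) of haem synthesis was not called. The median was 0.62, with a camera adjusted p of 0.012 and adjusted p = 0.188 with an estimated correlation.

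The targets of WNT, BMP, Notch and YAP signalling were lower for 7 of 39 members, with 0 higher, or 9 lower adjusted over the list alone. The count was 3 without DMSO replicate 3, 2 without GSK-J4 replicate 2 and 1 without GSK-J4 replicate 3. Besides CTGF, these included the Notch target HES1 (-0.78), which was lost without GSK-J4 replicate 2 (adjusted p = 0.092) or 3 (0.067). The list median was -0.20, with a camera adjusted p of 0.0056 and adjusted p = 0.336 with an estimated correlation. Of 27 immediate early and serum response genes, 2 were lower and 0 higher, or 9 lower adjusted over the list alone. They were KLF2 (-1.51) and ARC (-1.37), both lost without DMSO replicate 3 or any one GSK-J4 library (adjusted p up to 0.14 and 0.13), while 8 genes were lower without DMSO replicate 2. The median was -0.41, with a camera adjusted p of 0.0023 and adjusted p = 0.570 with an estimated correlation. Inflammatory genes (1 of 19 lower, 0 higher, also adjusted over the list alone) and interferon-stimulated genes (0 of 21 called by edgeR or DESeq2, also adjusted over the list alone, 6 at an unadjusted p below 0.05) had medians of -0.24 and 0.25. The inflammatory median was -0.52 without DMSO replicate 2 and -0.44 without GSK-J4 replicate 2, and the interferon median 0.38 without DMSO replicate 3. Each list had a camera adjusted p of 0.0496 and adjusted p = 0.215 with an estimated correlation. The inflammatory shift was lost without DMSO replicate 1 (0.20), DMSO replicate 3 (0.12) or GSK-J4 replicate 3 (0.22), and the interferon shift without DMSO replicate 1 (0.082), DMSO replicate 2 (0.096), GSK-J4 replicate 1 (0.061) or GSK-J4 replicate 2 (0.093). Both were also lost with DESeq2 size factors (0.0504 each), and the inflammatory shift with library totals (0.097). The inflammatory gene was TNFAIP6 (-0.95), which binds hyaluronan, lost without DMSO replicate 1, DMSO replicate 3, GSK-J4 replicate 2 or GSK-J4 replicate 3 (adjusted p up to 0.17), while 3 genes of the list were lower without DMSO replicate 2.

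Both mitochondrial ribosomal RNA genes rose with GSK-J4, by log2 fold changes of 1.64 (SE 0.14) and 1.93 (SE 0.21), and edgeR's adjusted p was 0.00013 and 0.00043. They lie at 1297 to 2272 and 2346 to 3966 of the mitochondrial genome in the file's coordinates. Their share of all counts was 0.0272% ± 0.00767 (SD, n = 3) with DMSO and 0.0876% ± 0.0144 (SD, n = 3) with GSK-J4. Of 8 mitochondrial transfer RNA genes, 4 rose, with a median of 2.20 over the 8. Their levels were low, with a summed CPM of 4.78, 4.20 and 6.20 in DMSO replicates 1, 2 and 3. In GSK-J4 replicates 1, 2 and 3 the sum was 13.70, 16.81 and 12.98 CPM. The 13 protein-coding genes of the mitochondrial genome had a median of 0.20 and a camera adjusted p of 0.209, with 0 called by edgeR, also adjusted over the list alone, 1 by DESeq2 and 4 at an unadjusted p below 0.05. The median was 0.10 without DMSO replicate 2 and -0.03 without GSK-J4 replicate 2. That list was shifted up without GSK-J4 replicate 1 with the preset correlation (camera adjusted p = 0.0053), and with all libraries it had adjusted p = 0.736 with an estimated correlation. Among 53 nuclear genes of the respiratory chain, COX5B (-0.51) was lower and 0 were higher, also adjusted over the list alone, with a median of -0.01 and a camera adjusted p of 0.636. COX5B was lost without DMSO replicate 3 (0.062), GSK-J4 replicate 2 (0.15) or GSK-J4 replicate 3 (0.12). Of 62 cytosolic ribosomal protein genes, edgeR and DESeq2 called 0, also adjusted over the list alone, and 4 had an unadjusted p below 0.05. Their median was 0.09, 0.03 without DMSO replicate 3, and -0.00 when libraries were scaled by their totals, where the list was no longer shifted. Camera gave an adjusted p of 0.012, against 0.20 without DMSO replicate 3, and adjusted p = 0.736 with an estimated correlation. Of the 34 lists tested, camera with its preset correlation called 20 shifted, 7 up and 13 down, against 0 with an estimated correlation, where the smallest adjusted p was 0.0849, and 11 with fry, which tests each list on its own. Fry called the contractile, fibrous matrix, mesenchymal, striated muscle, red blood cell, mitosis and DNA replication lists. The p53, integrated stress response, oxidative stress and interferon lists were also called by fry. Among those not called were the TGF-beta (fry adjusted p = 0.060), lens fibre (0.063), matrix protease (0.063) and cholesterol (0.089) lists.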

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

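The fit without chromosomes Z, W and MT was chosen after the data were seen, and all other settings were planned. With all libraries, 634 genes were called, 132 higher and 502 lower, 404 of them at least 2-fold. DESeq2 called 986 (304 higher), 633 of which were among the 634, and gave no adjusted p for 4178 genes. The FPKM fits called 411 with a pseudocount of 0.1 (320 lower) and 388 with 1 (87 higher, 301 lower, 230 at least 2-fold). Without a filter, 269 genes were higher. Leaving out 1 library gave 249 to 861 calls, 42 to 271 higher, 203 to 590 lower and 219 to 486 at least 2-fold. The cause was not tested, neither for these nor for the other differences, though a fit on fewer libraries has less power. Without chromosomes Z, W and MT, 628 genes were called. The other scalings, the stricter filter, limma-voom and robust estimation turned off gave 558 to 758. The share of lower genes was 79.2%, against 64.0% with the replicate block and 88.0% with library totals, which moved the median of all genes from 0.01 to -0.08. In each of these settings, 0 of the 634 genes were called with the opposite sign.

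Camera shifted 20 lists, and fry 11. With an estimated correlation 0 were shifted. The remaining fits gave 18 to 20. With the replicate block, the inflammatory list was not shifted (camera adjusted p = 0.082). List counts also moved. With FPKM and a pseudocount of 1, 9 integrated stress response genes were higher (14 in edgeR), and 5 TGF-beta (8), 3 WNT, BMP, Notch and YAP target (7), 3 cholesterol (6) and 0 basement membrane genes (3) were lower. DESeq2 called 6 matrix protease (3), 6 immediate early (2) and 4 hypoxia genes (1) lower and 6 lens fibre genes higher (1). The replicate block gave 11 lower cholesterol, 5 lower matrix protease and 6 higher oxidative stress genes (3). It also gave 6 higher lens fibre genes (1), and 6 immediate early (2), 3 developmental (1) and 1 macrophage genes (0) lower. In the hypoxia list 2 were higher and 5 lower (1 and 1), and in the chaperone list 2 and 4 (1 and 1). Leaving out DMSO replicate 1 gave 1 more higher gene in each of the macrophage, pigmented epithelium, interferon and cytosolic ribosomal lists and 1 more lower Polycomb gene. Leaving out DMSO replicate 2 gave 1 more lower gene in each of the p53, interferon and oxidative stress lists and 1 more higher gene in the red blood cell and the mitochondrially encoded lists, the latter also without GSK-J4 replicate 1. List medians moved as well. With library totals those of the p53, oxidative stress and interferon lists were 0.05, 0.04 and 0.15, and those of the hypoxia and mitochondrially encoded lists 0.04 and 0.10. The Polycomb and lens epithelial medians turned to -0.04 and -0.05 there, and 0 hypoxia genes were higher and 5 lower. With FPKM and a pseudocount of 1 those of the matrix protease, inflammatory, WNT, BMP, Notch and YAP target and developmental lists were -0.22, -0.11, -0.12 and -0.21. Leaving out 1 library turned the sign of the median in the Polycomb, basement membrane, lens epithelial, macrophage, leukocyte, endothelial, pigmented epithelium, retina, chaperone, mitochondrially encoded and respiratory chain lists, which were not shifted with all libraries. Of the 89 named genes that were called, 51 kept their call without any 1 library and 38 lost it at least once, 34 without GSK-J4 replicate 2. Another scaling ended 7 calls (ASNS, PSAT1, BNIP3, COL4A1, EPAS1, GJA1 and TNFAIP6). The FPKM fits ended 17, limma-voom 7 (ADAMTS9, ARC, COL4A1, EMX2, EPAS1, FLT4 and KLF2), the stricter filter 4 (COL4A1, EPAS1, FLT4 and TNFAIP6) and DESeq2 0. Without a filter, FN1 (adjusted p = 0.082), CRIP1 (0.098), ASNS, PSAT1, COL4A1 and TNFAIP6 were not called. With the replicate block, 1129 genes were called (406 higher), 625 of them among the 634. The block ended 1 call of a named gene, that of TNFAIP6 (edgeR adjusted p = 0.20). Deviations from the group means correlated at 0.30, 0.17 and 0.04 for the same numbers. Of 6 libraries, 5 correlated best with their own number, while GSK-J4 replicate 3 did so with DMSO replicate 2 (0.11). The second principal component held 18.8% of the variance. On it, DMSO and GSK-J4 lay at 26.62 and 23.02 for replicate 1, -11.32 and -0.56 for replicate 2, -19.53 and -18.22 for replicate 3. The W-linked sums at replicate 3 were far apart, at 906 and 15.1 CPM. Whether the numbers mark pairs therefore stays open, and so does the choice between the fits with and without the block.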

Other observations

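All tests of explanations in this part were chosen after the results they address had been seen, and the genes named in the next paragraph were chosen after their values were seen.

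PYCR1 and ALDH18A1, which encode enzymes of proline synthesis, had log2 fold changes with GSK-J4 of 1.36 and 1.45 (edgeR adjusted p = 0.0013 and 0.0015), PYCR1 from 69.6 ± 17.5 to 179 ± 26.8 CPM (SD, n = 3 each). The neutral amino acid transporter gene SLC1A4 (0.89) and MTHFD1L (0.78), of mitochondrial folate metabolism, were also called. A gene that the file describes as DNA damage inducible transcript 3 (ENSGALG00000031518), a stress-induced transcription factor, rose from 11.4 ± 3.23 to 40.5 ± 4.38 CPM (SD, n = 3 each). Next to the metallothioneins MT4L and MT3, the zinc transporter gene SLC30A2 rose from 0.889 ± 0.425 to 7.79 ± 1.03 CPM (SD, n = 3 each), a log2 fold change of 3.11, while SLC30A1 (0.42, adjusted p = 0.087) and the metal-sensing transcription factor gene MTF1 (0.19, adjusted p = 0.668) were not called. Among abundant genes, the actin-sequestering gene TMSB4X fell by 1.47 and the galectin gene LGALS1 by 2.57 on the log2 scale.

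The W-linked sums of 389 and 348 CPM in the replicates numbered 1 and of 935 and 760.0 CPM in those numbered 2 were close, whereas those numbered 3 had 906 and 15.1 CPM. The summed CPM of 560 genes of chromosome Z was 19090 to 21154 in DMSO and 22028, 21432 and 25919 in GSK-J4 replicates 1, 2 and 3. Of the 634 called genes, 18 lie on chromosome Z, 6 higher and 12 lower. Among them were PSAT1 and PCGF3, which were higher, and KLF9 and FST, which were lower.

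The lower contractile, matrix and mesenchymal lists could come from a different mix of sexes between the libraries, from scaling, from fewer mesenchymal cells, or from less expression per cell. With the W-linked sum as a covariate, the median group coefficient over the 83 members of the 3 lists was -0.75 (quartiles -1.38 and -0.14), against -0.74 without it, which argues against the mix of sexes as the cause. Under the other scalings, the highest of the 3 list medians was -0.64. These scalings moved the median of all genes only between 0.01 and -0.08. The values therefore argue only against the choice among these scalings as the cause. Fewer mesenchymal cells and lower expression per cell cannot be told apart, because lens epithelial cells also express part of these genes and no measurement here resolves cells. The members moved unequally, with an SD of 1.06 in log2 fold change and 18 of 83 above 0, and an effect of GSK-J4 on each cell remains an untested hypothesis.

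Most RNAs of the mitochondrial ribosomal and transfer RNA genes lack the long poly(A) tails that many library kits select. Their rise may therefore be technical, or it may reflect mitochondrial RNA in general. Counts at the transfer RNA genes were low, and whether they came from mature transfer RNA was not tested. The summed CPM of 11 nuclear structural RNA genes was 42.8 ± 10.5 with DMSO and 37.6 ± 2.01 with GSK-J4 (SD, n = 3 each), a log2 ratio of -0.18, with 0.18 as the highest of the library pairs. That argues against more non-polyadenylated RNA of every kind in the GSK-J4 libraries. The highest log2 fold change among the 13 mitochondrial protein-coding genes was 0.51, which argues against a rise of all mitochondrial RNA. A selective effect on mitochondrial ribosomal RNA, or a difference in RNA handling that spares nuclear structural RNA, stays open and was not tested.

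The rise of the integrated stress response could be the outcome of endoplasmic reticulum stress, which also raises chaperones, or of scaling. The chaperone list had a median log2 fold change of -0.0206 with an SD of 0.37 over its members, 0.64 below the stress response median. Of its members, 14 were above 0, among them XBP1 (0.67), and 14 below, among them CREB3L1 (-1.21). For the list as a set, that argues against endoplasmic reticulum stress as the whole cause. A part of such stress in the rise stays open. Under the other scalings the lowest median of the stress response list was 0.52, which argues only against the choice among these scalings as the cause. Other triggers of ATF4 were not tested and stay open.

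With 6 libraries there are 10 splits into groups of 3, too few for a share below 0.05. Only the real split, 1 of 10, gave as many as 634 changed genes, where the highest of the others gave 0, and likewise for the 404 genes changed at least 2-fold, where the highest was again 0. For shifted lists the real split gave 20 and the highest other 15, also 1 of 10. Each other split mixed both treatments within its groups, which adds to the spread there. Such splits therefore do not measure what would be called without a treatment effect.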
